A study of Mus musculus with 2 samples.

How the data were processed

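The samples were 2 biological replicates of whole liver from mouse embryos of 14.5 days, immunoprecipitated for H3K4me1 and sequenced. Per the labels, each replicate came from pooled male and female embryos of 1 strain background, and their biosamples differ. The deposited files were peak lists on the mm10 assembly, with 1 list per replicate, 1 from the pooled alignments of both, and 1 called replicated peaks. Per the file headers, replicate 1's list was derived from its alignments and 2 further files, replicate 2's from its alignments and 1 of these files, and the pooled list from both alignments and the same 2 files. What those further files hold, the aligner and the peak caller are not given in the sources used here. The replicated list was derived from both replicates' lists and the pooled list, per the file headers, and the rule is not given in the sources used here.

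Column 7 of each list is the authors' signal value of a peak, by the narrowPeak format named in the file headers, and it was used only to rank or filter peaks within a list. Columns 8 and 9 hold the authors' −log10 p-value and −log10 q-value of each peak, per the file headers. The lowest −log10 p was 2.01 in replicate 1's list, 2.00 in replicate 2's and 2.05 in the pooled list. No read counts were in the files used, so depth per replicate is unknown, and intervals on shares cover counting error over peaks only. A place without a peak is one that did not pass the authors' threshold, not one shown to lack the mark. Since replicate 1's list is longer, differences in coverage between the replicates' lists include how much was called in each.

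Peaks on chromosomes 1 to 19, X and Y were used. The reference was GRCm38 with GENCODE M21 protein-coding genes, the assembly the labels name. No peak reached past the end of its chromosome or into a run of N of 50 bp or more. The analysis ran in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9. Choices were fixed before the data were examined unless named as added.

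A peak counted as shared where the overlap covered at least 50% of either peak. Chance sharing came from 100 random placements of the other list's peaks within their chromosomes outside gaps, and, as an alternative, from a shift by 20 kb. Peak midpoints were assigned to promoter (within 1 kb of a TSS), exon, intron or intergenic sequence in that order and compared with 100 random placements (20 in alternatives). A gene's TSS was the start of its annotated gene model, and a symbol with several models kept the longest. Peak coverage was measured in bins of distance from the TSS from 250 bp to 50 kb.

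For each protein-coding gene the percent of bases within 50 kb of the TSS covered by peaks was computed. The mean over each of 18 gene lists was compared with 10000 random lists of the same size, drawn with replacement from genes in the same of 5 equal classes of gene density, by a two-sided permutation test with Benjamini-Hochberg adjustment over the 18 lists at 0.05. The lists were erythroid, heme synthesis, blood stem and progenitor, megakaryocyte, myeloid and macrophage, lymphoid, hepatoblast, mature hepatocyte, coagulation and complement, bile duct, endothelial, stellate and mesenchymal, neuronal, muscle, epidermal, chemosensory receptor, ribosomal protein and Hox genes. Of 30 erythroid and 22 coagulation and complement symbols, 29 and 21 were found in the annotation, and other lists were complete. These p-values describe the lists in these libraries, not a difference between conditions. Hoxa9 is in both the blood stem list and the Hox list.

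Peaks close to each other were joined into clusters ranked by covered bases. Densities of 14 motifs, on both strands, in the 500 bp at peak midpoints were divided by those in 500 bp segments 5 kb away that touched no peak, drawn to the same GC content in bins of 2%. Intervals of 95% came from 1000 bootstraps of chromosomes, and motifs with fewer than 20 sites in either set gave no ratio. The ratios of rare motifs also moved with the set of flanks drawn, so whether a rare motif passed is uncertain. The genes named were, in each fixed list, the 3 highest and the lowest by coverage, the 15 highest loci over all genes with 1 gene per 100 kb, the genes of the 10 top clusters, and Gata1, Klf1, Hbb-bt, Hba-a1, Alb and Hnf4a whatever their values. Not every gene that this rule takes is printed, and Epb41 is named as the neighbour of a top locus.

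Alternatives were each replicate's list alone, the pooled list, the stronger 50% of a list by signal value, other overlaps, windows, promoter widths, segment lengths and joining distances, peak numbers in place of coverage, other matching, 1 gene per locus, and promoter bases left out. Replicated peaks found in both replicates' own lists, and TSSs of all coding transcripts, were added after the data were examined.

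The steps were tested on simulated data. Lists made with 39.8% of peaks shared gave 40.3%. The shared peaks were copies shifted by a small part of their width, which the sharing rule always counts. Peaks were placed at random in lists of similar length, so this tested the counting only, not clustered lists of unequal length. Of 200 simulated lists of 20 genes per fold, the gene list test called 6% at p under 0.05 with no change, 70% with a 2-fold and 97% with a 4-fold change. Coverage was shuffled among genes within density classes here, so these rates do not cover lists whose genes share windows, such as Hox genes. Sequence made with a GATA density ratio of 1.24 gave 1.25 (interval 1.22 to 1.27).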

Results

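H3K4me1, the monomethylation of lysine 4 on histone H3 that is known to mark enhancers and the flanks of promoters, was mapped by ChIP-seq in the liver of mouse embryos at 14.5 days. At this stage the liver is the main site of red cell formation, so a whole-liver sample holds blood-forming cells beside hepatoblasts, the precursors of hepatocytes. The study had 1 group of 2 biological replicates, each from pooled male and female embryos, and no other tissue, age or treatment. The comparisons it allows are therefore replicate against replicate, and the marked genome against chance. The files gave 4 peak lists and no read counts, so the sequencing depth of each replicate is unknown. Replicate 1's list held 68109 peaks covering 31.2 Mb, with a median width of 304 bp. Replicate 2's list held 34531 peaks covering 16.0 Mb, with a median width of 328 bp. The authors' pooled list held 54144 peaks over 31.2 Mb. Their replicated list, used as the main peak set here, held 38687 peaks over 27.2 Mb, which is 1.03% of the assembled genome. A q-value under 0.05 was listed for 89.3% of replicate 1's peaks and 51% of replicate 2's. In each list 1 peak lay on an unplaced sequence and was left out.

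The first question was how far both replicates marked the same places. Replicate 2's peaks were mostly found again in replicate 1: 27754 of 34530 (80.4%, 95% Wilson interval 80 to 80.8%) shared at least 50% of their own or the other peak's length. In the other direction 24357 of 68108 peaks were shared (35.8%, interval 35.4 to 36.1%). With the other list's peaks placed at random within their chromosomes the shares were 1.86% and 0.951%, so the observed shares were 43.2-fold and 37.6-fold above this chance level. Chance was higher near marked regions: with each peak shifted by 20 kb the shares were 10.4% and 5.17%. Both lists covered 81.3% of replicate 2's bases in common and 41.6% of replicate 1's. The strongest sites were shared almost completely. Of the strongest 10% of each list by the authors' signal value, 91.9% were shared for replicate 1 and 99.3% for replicate 2. In the weakest 10% the shares were 16.4% and 72.9%. Shared peaks of replicate 1 had a median width of 566 bp, and those found in replicate 1 alone 247 bp. The shares moved with the definition: when both lists were held to the same length by p-value, 55.0% of replicate 1's and 65.8% of replicate 2's peaks were shared, and a mutual overlap of 50% gave 21.4% and 42.3%.

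**Figure D1:**
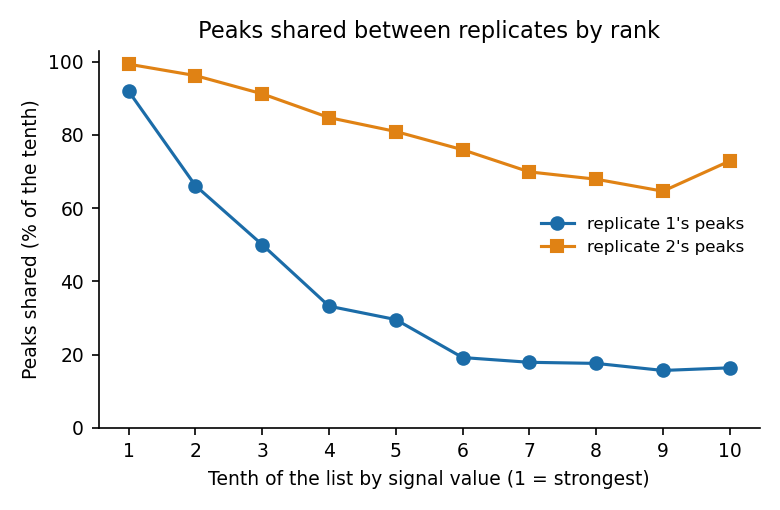
Share of peaks found in the other replicate's list (y axis, percent) for each 10% of a list ranked by its own signal value (x axis, 1 is the strongest), with replicate 1 as circles and replicate 2 as squares. Replicate 1 starts at 91.9% and ends at 16.4%, while replicate 2 starts at 99.3% and stays at 64.6% or above.

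The combined lists were then compared with both replicates' own lists. Each of the 38686 replicated peaks on the chromosomes was identical to a pooled peak. Of these, 23712 (61.3%) shared a peak with both replicates, 12072 with replicate 1 alone, 1533 with replicate 2 alone and 1369 with neither. Among the 15457 pooled peaks that the replicated list left out, 0 shared a peak with both replicates by this rule and 198 did at an overlap of 1 bp. The median signal in the pooled list was 4.31 for replicated peaks found in both replicates, 3.4 for the other replicated peaks and 3.03 for the peaks left out.

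The second question was where the marked sequence lay. Gene bodies held more of the replicated peaks than random placements did: 54.3% of peak midpoints were intronic and 6.14% exonic, against 37.3% and 3.60% for random placements. Promoters, taken as 1 kb either side of a protein-coding transcription start site (TSS), held 13.4% of peaks (interval 13.0 to 13.7%), against 1.73% at random. The promoter excess was 7.74-fold in the replicated list and 6.72 ± 0.153-fold (SD, n = 2) in the replicates' own lists. Intergenic sequence held 26.1% of peaks, 0.456 of the random share. Intergenic peaks were somewhat stronger than promoter peaks, with median signals of 3.92 and 3.75 and median widths of 537 and 432 bp. The promoter share depends on the definition: it was 30.2% within 2.5 kb of a TSS (4.23% at random), which left 43.6% intronic and 3.72% exonic, and 18.8% with the TSSs of all coding transcripts (2.74% at random).

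The mark was thinner on the TSS itself than beside it. Within 250 bp of a TSS 2.63% of bases were covered by replicated peaks, against 8.97% between 500 bp and 1 kb and 7.63% between 1 and 2 kb. Coverage fell to 3.23% at 2 to 5 kb, 1.30% at 10 to 50 kb and 0.323% beyond 50 kb. Relative to each list's genome-wide coverage the replicates gave 2.48 ± 0.235-fold (SD, n = 2) within 250 bp, 8.03 ± 0.460-fold at 500 bp to 1 kb and 0.326 ± 0.00837-fold beyond 50 kb. The difference between the first 250 bp and the flank was thus larger than the spread between replicates. With the TSSs of every coding transcript in place of 1 per gene, the 1 to 2 kb bin held 1.97 times the coverage of the first 250 bp, against 2.90 times in the main measure.

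**Figure D2:**
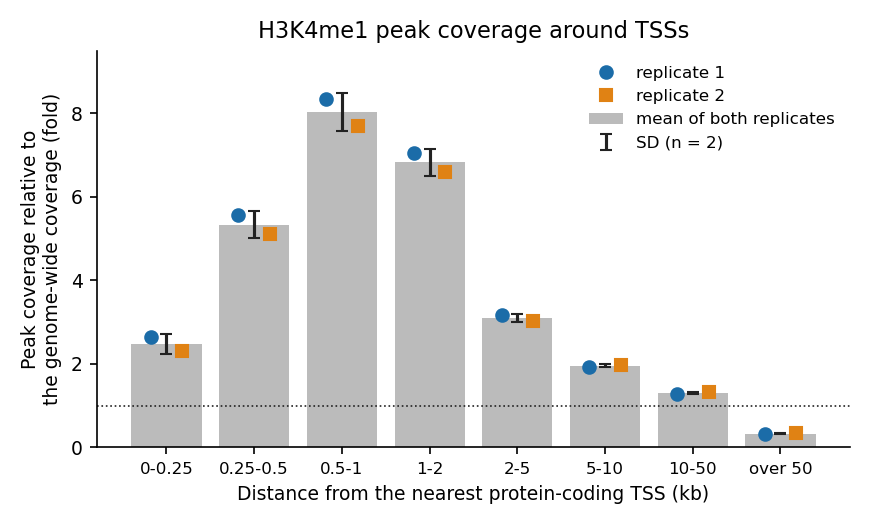
Peak coverage in bins of distance from the nearest protein-coding TSS (x axis, kb) relative to the genome-wide coverage of the same list (y axis, fold), with bars for the mean of both replicates, error bars for the SD (n = 2), and circles and squares for replicates 1 and 2. The mean rises from 2.48-fold in the first bin to 8.03-fold at 0.5 to 1 kb and falls to 0.326-fold beyond 50 kb.

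The third question was which genes carried the mark, measured as the share of bases within 50 kb of the TSS covered by replicated peaks. Over 21911 protein-coding genes the median was 0.776% and the mean 2.71%, and 40% of genes had no covered base. Replicate 2's shorter list gave a mean of 1.55% and replicate 1's 3.02%. Genes of red cell formation stood far above this. The 29 erythroid genes averaged 13.5%, which was 4.63-fold above random lists of the same size and gene density in the replicated list (two-sided permutation p = 0.0002, the smallest the 10000 random lists can give; adjusted p = 9.00e-04 over 18 lists) and 5.02 ± 0.759-fold (SD, n = 2) in the replicates' own lists. Of these genes 28 lay above the median of all genes and 14 in the top 10%.

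Zfpm1, which encodes the GATA1 cofactor FOG1, was covered over 50.4% of its window in the replicated list and 44.7 ± 6.47% (SD, n = 2) in the replicates' lists. Hba-a1, an adult α-globin gene, reached 34.9% (replicates 30.3 ± 5.8%), and Bcl2l1, which encodes the survival factor BCL-XL, 34.6% (replicates 30.6 ± 6.82%). The adult β-globin gene Hbb-bt had 13.7% (replicates 11.7 ± 4.94%). Klf1, a transcription factor of red cell maturation, had 7.76% (replicates 6.82 ± 2.76%) and Gata1, the master regulator of the lineage, 3.97% (replicates 3.69 ± 1.72%). Gata1 lies on chromosome X, where coverage was low, at a mean of 0.279% over 948 genes. The lowest erythroid gene was Ank1, which encodes ankyrin of the red cell membrane skeleton, at 0.673%, with no covered base in replicate 2's list. Its window was centred on the most upstream annotated TSS.

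Heme synthesis, blood stem and progenitor, and megakaryocyte genes also lay above random lists. Enzymes of heme synthesis averaged 8.50%, 2.44-fold above random lists (permutation adjusted p = 0.0211), and 9 of 9 lay above the median of all genes. They were led by Cpox at 19.1% (replicates 16.2 ± 3.47%, SD, n = 2), Fech at 16.5% (18.4% in replicate 1's list and 9.77% in replicate 2's) and Hmbs at 9.39% (7.14 ± 4.10%). Alas1, the non-erythroid form of the first enzyme, was lowest at 1.55% (0.985 ± 0.413%), and at 0 in the stronger 50% of peaks and in peaks found in both replicates. Blood stem and progenitor genes averaged 6.40% (3.02-fold, permutation adjusted p = 0.00432) but were split. Cbfa2t3, Lyl1 and Gfi1b, transcriptional regulators shared with the erythroid and megakaryocytic lineages, had 24.1%, 21.5% and 17.7% (replicates 18.8 ± 7.75%, 19.1 ± 5.52% and 16.4 ± 4.53%, SD, n = 2), while 6 of 20, among them Procr, had no peak in the window. Megakaryocyte genes averaged 5.17% (2.14-fold, permutation adjusted p = 0.0388), led by the platelet receptor gene Gp9 at 20.3%, Nbeal2 at 12% and F2rl2 at 11.9% (replicates 16.6 ± 3.83%, 10.1 ± 2.76% and 10.4 ± 3.84%, SD, n = 2). Ribosomal protein genes, present as a list of genes used by all cells, averaged 4.91% (1.47-fold, permutation adjusted p = 0.0168). The megakaryocyte call was kept in 8 of 12 alternatives, the ribosomal protein call in 10 and the heme synthesis call in 11.

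Liver cell lists did not stand above random lists. Hepatoblast genes averaged 1.81%, 0.684 of the random mean (permutation adjusted p = 0.410), and 12 of 25 had no peak within 50 kb. Apoe had 9.88%, Hnf1a 8.57% and Ahsg 5.08% (replicates 8.22 ± 4.54%, 7.32 ± 3.09% and 4.42 ± 2.30%, SD, n = 2). The albumin gene Alb had 0.245% (replicate 1 0.832%, replicate 2 0), the hepatocyte regulator gene Hnf4a 0.871% (1.63% and 0.394%), and Ttr, which encodes transthyretin, 0 (0.188% and 0). Genes of the mature hepatocyte averaged 2.08% (0.876 of random, adjusted p = 0.811 by permutation), with Hpd at 15%, Cyp1a2 at 9.14% and Slc10a1 at 5.97% (replicates 13.1 ± 4.64%, 7.76 ± 2.32% and 5.74 ± 2.21%, SD, n = 2), though Cyp1a2 had 0.26% in the stronger 50% of peaks. Coagulation and complement genes averaged 1.85% (0.779 of random, adjusted p = 0.637 by permutation), with Serping1 at 17.2% and Serpinf2 at 11.7% (replicates 13.9 ± 5.79% and 9.41 ± 3.17%, SD, n = 2). For the hepatoblast list 95% of random lists spanned 1.26 to 4.47%, so a difference inside that range was not detectable with 25 genes. A window takes in neighbouring genes, so a value is that of the locus, not of the named gene alone.

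Among other cell types of the liver, bile duct genes lay below random lists at 0.149% (0.0743 of random, permutation adjusted p = 0.0414), where Sox4 and Epcam alone had peaks, at 0.780% and 0.560%. The remaining 4 lists had no call. Myeloid and macrophage genes averaged 2.19% (0.801 of random), lymphoid genes 2.08% (0.690), endothelial genes 1.80% (0.732) and stellate and mesenchymal genes 0.466% (0.260), with permutation adjusted p-values of 0.637, 0.415, 0.637 and 0.0736. Fcgr1, Cd68 and Elane led the myeloid list at 9.07%, 8.64% and 6.74% (replicates 7.03 ± 3.51%, 6.73 ± 2.94% and 5.63 ± 2.67%, SD, n = 2), though Elane had 1.17% in the stronger 50% of peaks. Cd79a, Lck and Cd247 led the lymphoid list at 10.3%, 9.14% and 7.27% (replicates 8.94 ± 1.94%, 6.06 ± 3.25% and 7.07 ± 2.5%). Among endothelial genes Eng had 7.05%, Stab1 6.28% and Esam 5.96% (replicates 6.49 ± 3.94%, 4.28 ± 2.68% and 4.81 ± 3.58%). Reln, a stellate cell marker, had 5.62% (replicates 6.47 ± 1.7%), while 15 of the 18 stellate and mesenchymal genes had no peak. The bile duct call was kept in 9 of 12 alternatives, and the myeloid list passed the threshold with 20 kb windows, at 0.312 of random (permutation adjusted p = 0.0368).

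Hox, epidermal, chemosensory receptor and neuronal genes lay below random lists. The 39 Hox genes had 0 replicated peaks within 50 kb, against a random mean of 4.69%. The 11 epidermal genes averaged 0.0958% (0.0324 of random), with Sbsn as the only 1 with a peak, and the 1464 olfactory and vomeronasal receptor genes averaged 0.199% (0.0598 of random). These 3 lists had a permutation p of 0.0002, the smallest possible (adjusted p = 9.00e-04). Neuronal genes averaged 0.605% (0.285 of random, permutation adjusted p = 0.0315), with Slc17a7 at 6.59% (replicates 5.78 ± 3.93%, SD, n = 2) and 17 of 22 without a peak. Muscle genes averaged 1.09% (0.486 of random) and did not pass (permutation adjusted p = 0.201). The neuronal call was kept in 10 of 12 alternatives. Windows of clustered genes overlap: with 1 gene per locus, 6 Hox loci had a permutation p of 0.0028 (adjusted p = 0.009) and 443 receptor loci a value of 0.109 of random (permutation adjusted p = 0.0018). Genes over 100 kb apart counted as separate loci, so 1 gene cluster could give several. The test treated these as independent.

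**Figure D3:**
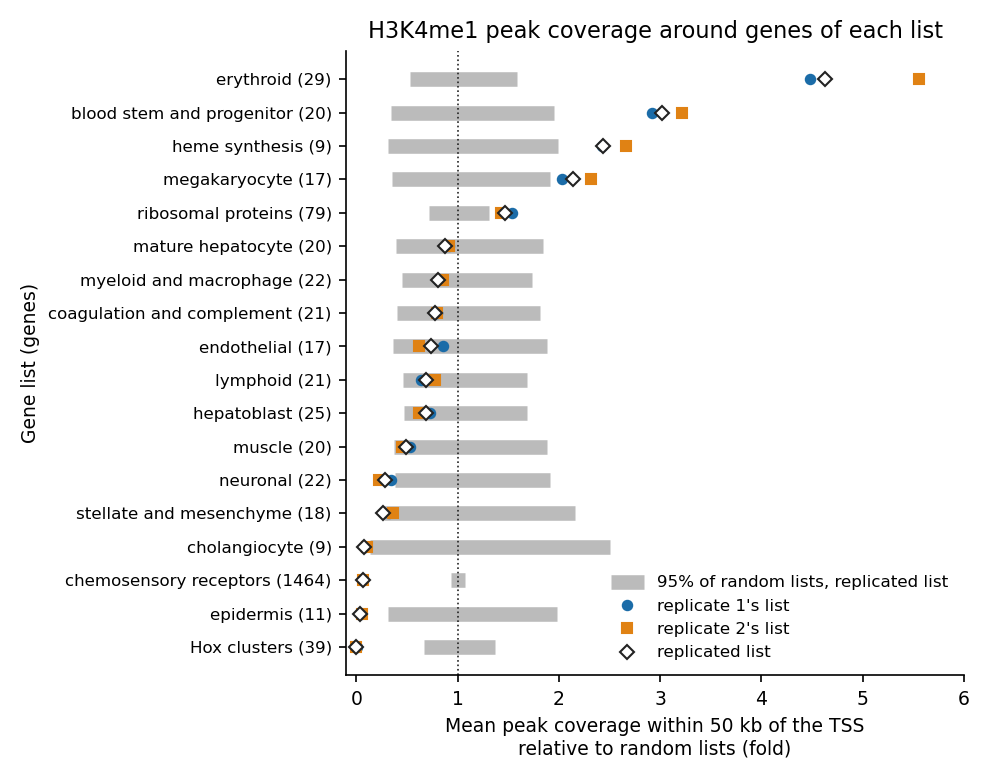
Mean peak coverage within 50 kb of the TSS relative to the mean of random lists matched on gene density (x axis, fold) for 18 gene lists (y axis, genes in parentheses), with diamonds for the replicated list, circles and squares for replicates 1 and 2, and grey bars for 95% of random lists of the replicated set. Erythroid genes lie at 4.63-fold in the replicated list, and Hox, epidermal and chemosensory receptor genes near 0.

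The loci with the densest marking were read from all genes, keeping 1 gene per 100 kb. Hipk2, which encodes a kinase, led with 56.6% of its window covered by 42 peaks (replicates 48.2 ± 14.9%, SD, n = 2), followed by Zfpm1, Cd47 at 36.9% (replicates 31.5 ± 7.77%) and Nprl3 at 36.2% (replicates 31.1 ± 6.31%). The Hipk2 window also holds the TSS of Tbxas1. CD47 is the surface signal that protects red cells from uptake by macrophages, and introns of Nprl3 are known to hold the α-globin enhancers. Bmp2k (34.8%, replicates 28.8 ± 12.6%), Bcl2l1, Lpcat1 (34.5%, replicates 29.8 ± 6.71%), Hectd4 (34.4%, replicates 28.8 ± 7.30%), Pnpo (33.4%, replicates 27.6 ± 6.75%) and Cpeb4 (33.1%, replicates 28.1 ± 8.19%) followed. The next 5 were Nol4l, Btg2, Gm10300, Ranbp10 and Frs2, at 32.4%, 31.6%, 31.5%, 31.4% and 29.8% (replicates 27.8 ± 7.86%, 26.8 ± 7.37%, 25.6 ± 8.72%, 25.7 ± 6.07% and 22.5 ± 7.50%, SD, n = 2). Gm10300 lies beside Epb41, a red cell membrane gene of the erythroid list that had 31.1% (replicates 25.2 ± 8.72%, SD, n = 2). In the map of the Nprl3 window on chromosome 11, replicate 1 had 41 peaks, replicate 2 had 29 and the replicated list 26.

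**Figure D4:**
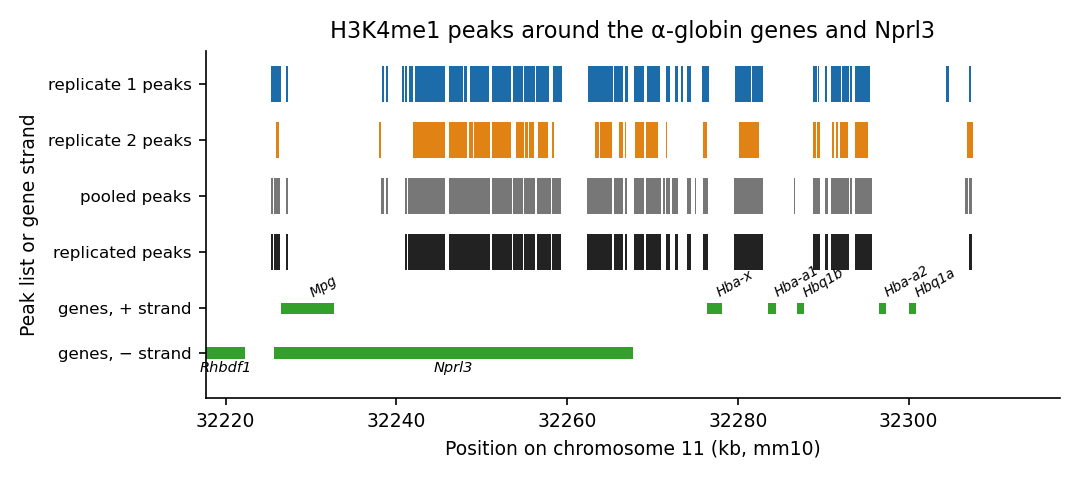
Peaks of the 4 lists (upper rows) and protein-coding genes by strand (lower rows) within 50 kb of the Nprl3 TSS on chromosome 11 (x axis, kb, mm10). Peaks of all lists cluster over the introns of Nprl3 and around Hba-a1, and the replicated list has 26 peaks in the window.

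Peaks lying close together were joined into clusters. The 38686 peaks formed 10936 clusters, of which 3723 were single peaks and 725 held 10 or more. The 546 clusters with most covered bases held 31.6% of all covered bases. The cluster with most covered bases spanned chromosome 6, 38772601 to 38992920, across the TSSs and parts of the gene bodies of Hipk2 and Tbxas1, with 66 peaks covering 74.7 kb (62.4 ± 22.3 kb in the replicates, SD, n = 2). It lay within gene bodies over 100% of its length, and 1.87% of it was exonic. The cluster at Bmp2k (chromosome 5, 96881233 to 97034271) had 55.7 kb covered (46.5 ± 17.0 kb in the replicates) and lay mostly outside genes, with 23.9% in gene bodies. Zfpm1 (chromosome 8, 122269065 to 122350279) had 55.6 kb covered (48.9 ± 7.48 kb in the replicates), or 68.5% of the cluster's length. Clusters at Klf13, Lpin2, Cd47, Cd24a and Cpeb4 had 54.8, 52.1, 47.4, 46.8 and 41.8 kb covered (46.8 ± 13.4, 45.0 ± 11.6, 40.5 ± 11.7, 39.4 ± 9.65 and 35.4 ± 9.20 kb in the replicates, SD, n = 2). The ninth, on chromosome 7 from 90019519 to 90109533, lay wholly in intergenic sequence 20680 bp from the TSS of Picalm, which encodes an endocytic adaptor, and had 38.9 kb covered (35.3 ± 5.85 kb in the replicates). The last of these 10, at Prkar2b on chromosome 12, had 38.3 kb covered (38.2 kb in replicate 1's list and 23.9 kb in replicate 2's). All 10 were among the top 50 clusters of each replicate's own list, and 7 were with peaks joined within 5 kb.

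The last question was which transcription factor motifs were denser at peaks than in nearby sequence of the same GC content. Several motifs of red cell regulators were, and so were some others. GATA sites were 1.35 times as dense in the 500 bp at peak midpoints as in flanks (95% interval 1.32 to 1.37), and the composite GATA and E-box site bound by GATA1 and TAL1 2.06 times as dense (1.96 to 2.17). The NFE2 site was 2.48 times as dense (2.08 to 2.99), on 352 sites in peaks and 142 in flanks. The replicates' own lists gave 1.29 ± 0.0233 for GATA, 1.90 ± 0.0545 for the composite and 2.59 ± 0.0813 for NFE2 (SD, n = 2). PU.1-type ETS sites (1.16, interval 1.09 to 1.23), FOXA sites (1.12, interval 1.06 to 1.18) and KLF sites (1.10, interval 1.06 to 1.13) had smaller excesses. The FOXA excess, of a motif whose factors are in the hepatoblast list, passed in all 7 alternatives, at 1.075 to 1.198. The ETS excess did not pass in the stronger 50% of peaks (1.05, interval 0.943 to 1.18) or in peaks found in both replicates (1.10, interval 0.992 to 1.21), nor the KLF excess in 200 bp segments (1.02, interval 0.98 to 1.06). The C/EBP site, at 1.28 (1.09 to 1.58), fell to 0.994 among peaks found in both replicates and did not pass in replicate 2's list (1.13, interval 0.954 to 1.34) or in the stronger 50% (1.19, interval 0.922 to 1.67). Sites of HNF4, RUNX, REST and the POU and SOX pair had intervals that included 1. Of these, HNF4 and the POU and SOX pair passed in replicate 1's list, at 1.19 (1.02 to 1.42) and 1.11 (1.02 to 1.2), and RUNX fell below 1 there, at 0.969 (0.951 to 0.991). The HNF4 call changed with the flanks drawn. In 200 bp at the same peak midpoints it was 1.05 (0.823 to 1.47) with 1 set of flanks and 1.40 (1.07 to 1.89) with another. Among the motifs chosen as controls from other tissues, OTX and CRX sites were depleted at 0.852 (0.823 to 0.880), but MEF2 sites were enriched at 1.60 (1.37 to 1.83). The MEF2 ratio was lower in the lists of replicate 1 (1.29) and replicate 2 (1.40) and without GC matching (1.28). Mef2c was itself in the megakaryocyte list, so MEF2 may not be a clean control, but this was not tested. The MEF2 result therefore leaves open that a motif excess in these peaks need not reflect a cell lineage. The HNF1 motif had 4 sites in peaks and 2 in flanks, too few for a ratio.

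**Figure D5:**
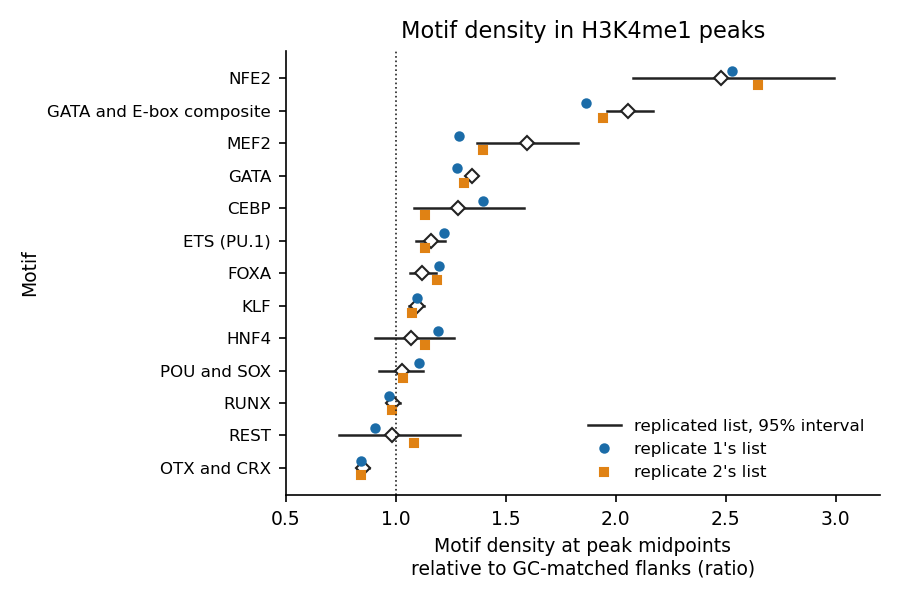
Motif density in 500 bp at peak midpoints relative to GC-matched flanks (x axis, ratio) for 13 motifs (y axis), with diamonds and lines for the replicated list and its 95% interval and circles and squares for replicates 1 and 2. NFE2 (2.48) and the GATA and E-box composite (2.06) lie highest, and OTX and CRX (0.852) lowest.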

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

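Peaks found in both replicates and TSSs of all transcripts were alternatives chosen after the data were examined. Of 216 gene list values under 12 alternatives, 200 kept their side of the threshold, 12 no longer passed and 4 newly passed. Hox, epidermal, chemosensory, erythroid and blood stem lists passed in all 12, the erythroid fold ranging from 3.27 to 5.55. Hepatoblast genes never passed, at 0.482 to 0.786 of random. Megakaryocyte genes no longer passed in the stronger 50% of peaks (2.32), without density matching (1.90), matched on gene length (1.99) or without promoter bases (2.09). The stronger 50% also ended the ribosomal protein call (1.40), which left 3 lists higher than random. Windows of 20 kb ended the ribosomal protein (1.32) and bile duct (0.0923) calls and added the myeloid list (0.312). Windows of 100 kb ended the heme synthesis (1.89) and neuronal (0.524) calls. One gene per locus ended the neuronal call (0.304). Bile duct genes also failed without promoter bases (0.0829), and across the replicates' own lists ranged from 0.0814 to 0.108, failing in replicate 2's. Stellate and mesenchymal genes passed by number of peaks (0.217), without density matching (0.172) and matched on gene length (0.171). With 100 kb windows the myeloid (1.11), mature hepatocyte (1.06) and endothelial (1.05) lists, which did not pass, lay above random and not below. The causes of these changes were not tested.

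The shared share was 40.4% of replicate 1's and 87.6% of replicate 2's peaks at 1 bp, 21.4% and 42.3% at 50% of both peaks, 35.3% and 77.7% in the stronger 50%, and 55.0% and 65.8% at equal length, and merging overlapping peaks changed neither. Shifting peaks by 20 kb raised the chance share to 5.17% and 10.4%. The promoter excess was 7.05-fold in the stronger 50%, 7.06 in peaks found in both replicates, 7.15 within 2.5 kb, 6.85 with all TSSs, and 6.61 to 6.83 in the replicates' lists. Coverage at 1 to 2 kb over that within 250 bp was 2.74 in the pooled list, 3.03 in the stronger 50%, 1.97 with all TSSs, and 2.67 to 2.85 in the replicates. Coverage at 1 to 2 kb over the genome was 6.46 in the stronger 50%, 6.86 in peaks found in both replicates, 6.10 with all TSSs, and 6.6 to 7.06 in the replicates. Of 91 motif values 80 kept their call, 5 no longer passed (C/EBP, ETS and KLF) and 5 newly passed (HNF4, RUNX, and POU and SOX). C/EBP turned to 0.994 in peaks found in both replicates, and REST, RUNX, and POU and SOX, whose main intervals included 1, lay on either side of 1. HNF4 was 1.33 (1.03 to 1.76) in the stronger 50%, and RUNX 0.964 (0.937 to 0.994) in 200 bp segments. Of 390 named-gene values 294 differed from the main value by no more than the SD of the replicates, and 96 by more. That SD comes from the replicates' own lists, which were among the alternatives and differ in length, so this count does not measure robustness. HNF1 had too few sites for a value. Read depth is unknown, so whether replicate 2 missed weaker sites cannot be told from the lists alone. Joining peaks within 5 kb kept 7 of the 10 largest clusters in the top 50. Clusters of 10 or more peaks, 725 in the main set, numbered 1722 in replicate 1's list and 702 in replicate 2's. There were 1250 in the pooled list and 187 in the stronger 50%. No paired analysis was possible because the study has 1 group.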

Other observations

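The gene lists and the chemosensory and ribosomal protein values of the next 2 paragraphs, and the coverage-matched test on blood and liver lists, were chosen after the data were examined. The other tests of this section were chosen after each pattern was seen. Iron handling genes, without those of the erythroid list, averaged 8.22% of bases within 50 kb covered by replicated peaks, 3.01-fold above random lists (permutation adjusted p = 0.0012 over 3 lists), and 3.33-fold and 2.83-fold in the lists of replicates 2 and 1. Glrx5, needed for iron-sulfur cluster assembly, had 23.9%, the ferritin gene Fth1 18.4% and the ferrireductase gene Steap3 15.3% (replicates 18.4 ± 6.73%, 16.4 ± 4.15% and 12 ± 2.53%, SD, n = 2). Autophagy and mitochondrial clearance genes averaged 4.98% (2.06-fold, permutation adjusted p = 0.018). The highest were Atg2a at 15.7%, Wipi1 at 11.8% and Atg14 at 11.6% (replicates 12.6 ± 3.75%, 10.7 ± 4.12% and 10.7 ± 1.11%, SD, n = 2). Bnip3l, the receptor for mitochondrial removal from reticulocytes, ranked 10 of 22 at 4.86% (replicates 4.65 ± 1.30%), below the list's mean. Glycolysis genes averaged 4.72% (1.48-fold) and did not pass (permutation adjusted p = 0.187). Pklr, the pyruvate kinase gene of liver and red cells, led them at 15.5% (replicates 14.3 ± 5.99%).

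Chemosensory receptor genes were sparsely marked, yet 5 of 1464 lay in the top 10% of all genes. Of these 5, Olfr66, Olfr64 and Olfr65 stood next to the β-globin genes on chromosome 7, at 26.2%, 25.1% and 23%, with TSSs 72.3, 80.5 and 89.5 kb from that of Hbb-bt. The other pair, Vmn1r4 and Olfr1396, had 20.5% and 8.71%. The 19 receptor genes within 200 kb of Hbb-bt averaged 5.75%, and the other receptor genes 0.126%.

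Chromosome X carried few peaks: 273 replicated peaks, or 1.67 per Mb, against 16.0 per Mb on autosomes, and no covered base lay near 81.7% of X genes, against 37.6% of autosomal genes. The 4 ribosomal protein genes on X averaged 0.396% and the 75 on autosomes 5.16%, while Alas2, the erythroid heme enzyme, was among the most covered X genes at 6.11%. Gene, repeat and GC content is argued against as the whole cause, because 100 kb windows of autosomes matched on all of these left an X ratio of 0.249 (95% interval 0.182 to 0.311), where single autosomes ranged from 0.826 to 1.26. Lower X copy number in male cells may contribute but cannot be told apart from other causes, since both samples pool the sexes. The ratio was 0.263 (0.195 to 0.321) in replicate 2's shorter list and 0.364 (0.275 to 0.446) in replicate 1's, and 0.141 in replicate 1's strongest 10%, from which a lower signal on X would itself remove peaks, so that value, used in place of a planned test of strongly marked windows near TSSs that was not run, decides nothing.

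Replicate 1's list was longer than both replicate 2's and the pooled list. Of replicate 1's strongest 10%, 91.9% was shared, against 16.4% of its weakest, as lower detection power in replicate 2 would give. This gradient cannot decide for lower power, since weak peaks of replicate 1 that are not true sites would also go unshared. Median widths differed too, at 983 bp in the strongest 10% and 238 bp in the weakest. Replicate 1's list was also derived from 2 further files and replicate 2's from 1. Of replicate 1's 18534 peaks missing from the pool, 99.7% were also missing from replicate 2, as they would be if replicate 2 diluted them, against 51% of the peaks that the pool kept, but this test is weak because a peak found in both replicates would seldom leave the pool. Different shares of blood and liver cells in the samples cannot be told apart from power: the log2 ratio of replicate 1 to replicate 2 coverage was 0.53 higher for hepatoblast than for erythroid genes (permutation p = 0.0236 against lists matched on gene density), but matching on coverage gave p = 0.267, and the other liver lists sat near the all-gene ratio of 0.96 (mature hepatocyte 0.98, coagulation and complement 0.97) while neuronal genes, from outside the liver, were above hepatoblast genes (1.57 against 1.18). How much of the difference is depth stays open, as read depth is unknown.

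Many neighbouring peaks lay 100 to 600 bp apart with no called peak between them, and the hypothesis was that bound sites lie in the gap. In 200 bp segments at 10109 such gaps, which in gaps under 200 bp take in peak bases, GATA sites were 1.54 times as dense as in GC-matched flanks (95% interval 1.47 to 1.60), above the 1.39 (1.36 to 1.42) in 200 bp at the midpoints of all peaks and above the peaks beside the gaps, whose interval was 1.19 to 1.30. The composite GATA and E-box site reached 4.33 (3.94 to 4.88) in gaps against 2.15 (1.95 to 2.37) at midpoints, and KLF sites 1.67 (1.5 to 1.85) against 0.989 (0.945 to 1.03). The excess in gaps was not limited to motifs of red cell regulators. MEF2 sites, chosen as a control, were at 1.78 (1.07 to 2.96) in gaps and 2.79 (1.91 to 4.56) at the peaks beside them. RUNX sites in gaps were at 1.08 (1.01 to 1.16). FOXA sites in gaps were at 0.990 (0.833 to 1.19), and ETS, HNF4, C/EBP, OTX and CRX, and POU and SOX sites also had intervals that included 1. The GATA and composite values are such as methylated nucleosomes on both sides of bound GATA sites could give. This remains a hypothesis, as binding was not measured in these samples.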
